A study of Mus musculus with 17 samples.

How the data were processed

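RNA of B cells from WT (n = 3), Sf3b1 MT (n = 3), Atm MT (n = 6), DM (n = 3) and DM-CLL (n = 2) mice was prepared with the PrepEase RNA Spin kit and NEBNext Ultra poly(A) libraries, per the labels. The authors deposited TPM (transcripts scaled to a fixed total per library) for 18554 gene symbols in 17 libraries, to 2 decimals. The submitters' processing notes name STAR and the mm10 genome. The quantifier, the annotation, the versions and any filter are not stated in the sources used here. The listed TPM of a library sum to 43.1% to 59.7% of the full total, so the values were scaled over features that the table does not list. No counts are given: the depth is unknown, and neither counting intervals nor detection floors could be computed. The table holds 2 immunoglobulin variable genes, so clonal use of variable genes could not be measured.

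Of the symbols, 3711 were at 0 in every library, and 9898 with a TPM of at least 1 in at least 2 libraries were tested. Values were log2-transformed after adding 1. Groups were taken from the genotype labels. The comparisons were Sf3b1 MT against WT, Atm MT against WT, DM against each of WT, Atm MT and Sf3b1 MT, the interaction of the lesions (DM − Sf3b1 MT − Atm MT + WT), and DM-CLL against DM and against WT. The last pair came from a fit of all 17 libraries and the others from a fit of the 15 libraries without DM-CLL. Fits used limma 3.58.1 in R 4.3.3, with moderation along a mean trend, 2-sided tests and Benjamini-Hochberg adjustment over the genes of a comparison, at a threshold of 0.05. Lists of genes with shared functions or cell types, 36 in all, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. The 34 lists with at least 5 tested genes were used, and their p-values were adjusted over the tests of all lists and comparisons. Members were also adjusted over the list alone. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. On simulated data with 200 changed genes, the design recovered 39% to 75% of 2-fold and 85% to 98% of 4-fold changes, depending on the comparison. The simulation drew independent normal values for each gene and changed only genes above a minimum mean. It held no shift of whole libraries and no correlation between genes, so these shares can overstate recovery in the real libraries.

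The comparisons, the lists and the rule for naming genes were fixed before the data were examined. The rule names Sf3b1 and Atm, then genes that passed, had a mean of at least 5 TPM in the higher group and had every library of one group above every library of the other. Of these, the 10 largest rises and 10 largest falls are named for Sf3b1 MT against WT, DM against WT and DM-CLL against DM, and 5 of each for the others. Predicted genes, pseudogenes, immunoglobulin and T-cell receptor segments, mitochondrial genes, Xist and Y-linked genes were left out of the naming. Where no gene passed, the 3 with the smallest p are named. Up to 4 members of each called list with the largest change in its direction follow, and B-cell and CLL genes chosen in advance in the comparisons with DM-CLL. Positions came from GENCODE release M21 on GRCm38, in which 18288 symbols matched once, 9734 of them tested.

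Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, median-ratio scaling over the 7769 genes with at least 1 TPM in every library, removal of immunoglobulin genes with the remaining table rescaled to a common total, library weights, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Added after the data were seen were fits without Atm MT replicates 1 to 4, with Xist as a covariate, and, for DM-CLL, without ribosomal protein genes and with the rest rescaled, and with all listed genes kept and rescaled to a common total. When a DM-CLL library was left out, the remaining one was assumed to vary like the other groups. For chromosomes, each gene's log2 value was set against its mean over the other non-leukaemic libraries, the library's median over all genes was subtracted, and the median was taken per autosome. Transcript-level and splicing changes could not be measured from gene-level TPM.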

Results

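Poly(A) RNA from B cells of C57BL/6 mice, which the titles call old, was sequenced in 17 libraries of 5 groups. Wild type (WT, n = 3) was set beside mice with a B cell-restricted Sf3b1 mutation (Sf3b1 MT, n = 3), mice with an Atm deletion (Atm MT, n = 6) and mice with both lesions (double mutant, DM, n = 3). The last group, DM-CLL (n = 2, replicates 4 and 5), carries both lesions and is labelled as chronic lymphocytic leukaemia (CLL). The labels do not say whether replicates are separate mice. Expression was given as TPM for 18554 gene symbols, of which 9898 were tested. Read depth is unknown, so the precision of single values cannot be given. Pearson's r of log2 values across genes was 0.875 to 0.981 between pairs of libraries. Values are mean TPM ± SD, changes are log2 ratios ± SE where an error is given, and coordinates are those of mouse genome build GRCm38. The verbs rose and fell are used for genes that passed an adjusted p of 0.05. For each gene named among the largest rises and falls, every library of one group lay above every library of the other.

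The targeted genes come first. Sf3b1, which encodes a core subunit of the U2 spliceosomal particle (chromosome 1, 54985169 to 55027481), measured 105 ± 8.51 TPM in WT (SD, n = 3), 69.9 ± 19.3 in Sf3b1 MT, 141 ± 31.1 in Atm MT (n = 6), 57.4 ± 17.1 in DM and 139 ± 1.83 in DM-CLL (n = 2). It fell in DM against Atm MT by 1.30 on the log2 scale (adjusted p = 0.0161) and rose by 1.30 in DM-CLL against DM (adjusted p = 0.00249). Without DM replicate 3 the fall did not pass (−1.06, adjusted p = 0.102), and the change in Sf3b1 MT against WT did not pass either (−0.62, adjusted p = 0.417). Atm, which encodes a kinase that signals DNA double-strand breaks (chromosome 9, 53439149 to 53536740), measured 7.64 ± 1.20 TPM in WT, 5.26 ± 1.94 in Sf3b1 MT, 7.50 ± 4.23 in Atm MT, 3.41 ± 0.789 in DM and 8.49 ± 1.0 in DM-CLL. Its log2 ratio to WT was −0.13 in Atm MT (adjusted p = 0.949) and −0.98 in DM (adjusted p = 0.131), neither passing. It rose in DM-CLL against DM (log2 1.12, adjusted p = 0.0378), a call lost after median-ratio scaling (0.67, adjusted p = 0.213) and in each of the 5 omissions: DM replicates 1, 3 and 6 (adjusted p = 0.0537, 0.109 and 0.0539) and DM-CLL replicates 4 and 5 (adjusted p = 0.111 and 0.137). The Atm level therefore does not separate the groups with the Atm lesion from the others. The labels do not say which part of the gene was deleted, and gene-level TPM do not resolve exons.

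The first question was what the Sf3b1 mutation alone changes in B cells. Fcgr2b, the inhibitory Fc receptor of B cells (chromosome 1, 170958617 to 170976547), fell from 177 ± 16.9 TPM in WT to 64.4 ± 8.48 in Sf3b1 MT (SD, n = 3 each; log2 −1.45 ± 0.20, adjusted p = 0.0128). Cd80, a costimulatory ligand of memory B cells (chromosome 16, 38455561 to 38496335), fell from 17.6 ± 3.90 to 3.32 ± 0.931 TPM (log2 −2.11 ± 0.30, adjusted p = 0.0129). Fzd6, a Wnt receptor (chromosome 15, 39006034 to 39038188), fell from 7.85 ± 4.43 to 0.947 ± 0.244 TPM (log2 −2.08 ± 0.28, adjusted p = 0.0128). Ms4a6c fell from 35.6 ± 2.43 to 13.2 ± 1.15 TPM and Cdk14, a cyclin-dependent kinase, from 5.05 ± 0.290 to 1.70 ± 0.287 TPM. The other genes that fell were Gm1965 and Hoxa7, singled out after their values were seen.

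Among fixed lists, the 13 tested genes of age-associated and memory B cells all had log2 ratios below 0 in Sf3b1 MT, with a median of −1.08, or −0.96 relative to all genes. Cd80 passed over all genes and 9 members fell when adjusted over the list alone, and the list test gave adjusted p = 1.07e-10, against adjusted p = 0.347 with an estimated correlation. Its members Nt5e (17.6 ± 7.72 to 2.61 ± 0.201 TPM) and Tbx21, the transcription factor T-bet (21.5 ± 1.29 to 6.07 ± 1.59 TPM), did not pass over all genes. All 19 tested genes of the unfolded protein response also had log2 ratios below 0 (median −0.47), with 0 passing over all genes and 4 lower when adjusted over the list alone. Hspa5, the main chaperone of the endoplasmic reticulum, measured 338 ± 116 in WT and 166 ± 32.2 TPM in Sf3b1 MT, and Hsp90b1 454 ± 205 and 174 ± 48.8 (list adjusted p = 1.03e-05; adjusted p = 0.475 with an estimated correlation). The platelet list stood higher (median 0.58, all 8 members above 0; adjusted p = 1.06e-07; adjusted p = 0.367 with an estimated correlation), with 3 members higher when adjusted over the list alone. Markers of other cells were also called higher, with medians of 0.58 for erythroid (adjusted p = 0.00240), 0.38 for neutrophil (adjusted p = 0.00161) and 0.14 for macrophage genes (adjusted p = 0.0141), as were histone genes without poly(A) tails (0.15, adjusted p = 3.29e-04). These lists had adjusted p = 0.618 to 0.854 with an estimated correlation, and 0 of their members passed over all genes or over the list alone in limma. Left-out libraries ended the erythroid call (WT replicate 3, 0.07; Sf3b1 MT replicate 2, 0.02; replicate 3, 0.49), the neutrophil call (WT replicate 1, −0.11; Sf3b1 MT replicate 3, 0.09) and the macrophage call (WT replicate 1, −0.14). After median-ratio scaling none of these 4 lists was called. Ribosomal protein genes had a median of 0.15, with 69 of 81 members above 0 (adjusted p = 2.66e-11; adjusted p = 0.721 with an estimated correlation). The list means overlapped, at 10.95, 10.35 and 10.77 in WT and 10.93, 11.04 and 10.5 in Sf3b1 MT. The lowest of each group, WT replicate 2 and Sf3b1 MT replicate 3, were libraries whose listed TPM summed to 44.1% of the full total.

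In limma, 7 genes fell and 0 rose between Sf3b1 MT and WT, with 1047 genes at an unadjusted p below 0.05. The median log2 ratio of all genes was −0.11, and after median-ratio scaling 3 of the same genes fell, with Cd80 (adjusted p = 0.0539) and Cdk14 (adjusted p = 0.0685) among those lost. The count was 2 without WT replicate 1, 1 without WT replicate 2, 23 without WT replicate 3, 4 without Sf3b1 MT replicate 1, 0 without replicate 2 (471 at an unadjusted p below 0.05), 1 without replicate 3 and 13 without Atm MT replicate 4. It was 0 with only these groups fitted (1397 at an unadjusted p below 0.05) and 0 with Xist as a covariate (920), an alternative added after the data were seen. Xist, the transcript of the inactive X chromosome, was at most 0.03 TPM in each Sf3b1 MT library and at 38.6, 47.0 and 0.08 TPM in WT. Of these 6 omissions Fzd6 kept its call in 4, Fcgr2b in 3, Cd80 in 2, and Ms4a6c and Cdk14 in 1 each.

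**Figure D1:**
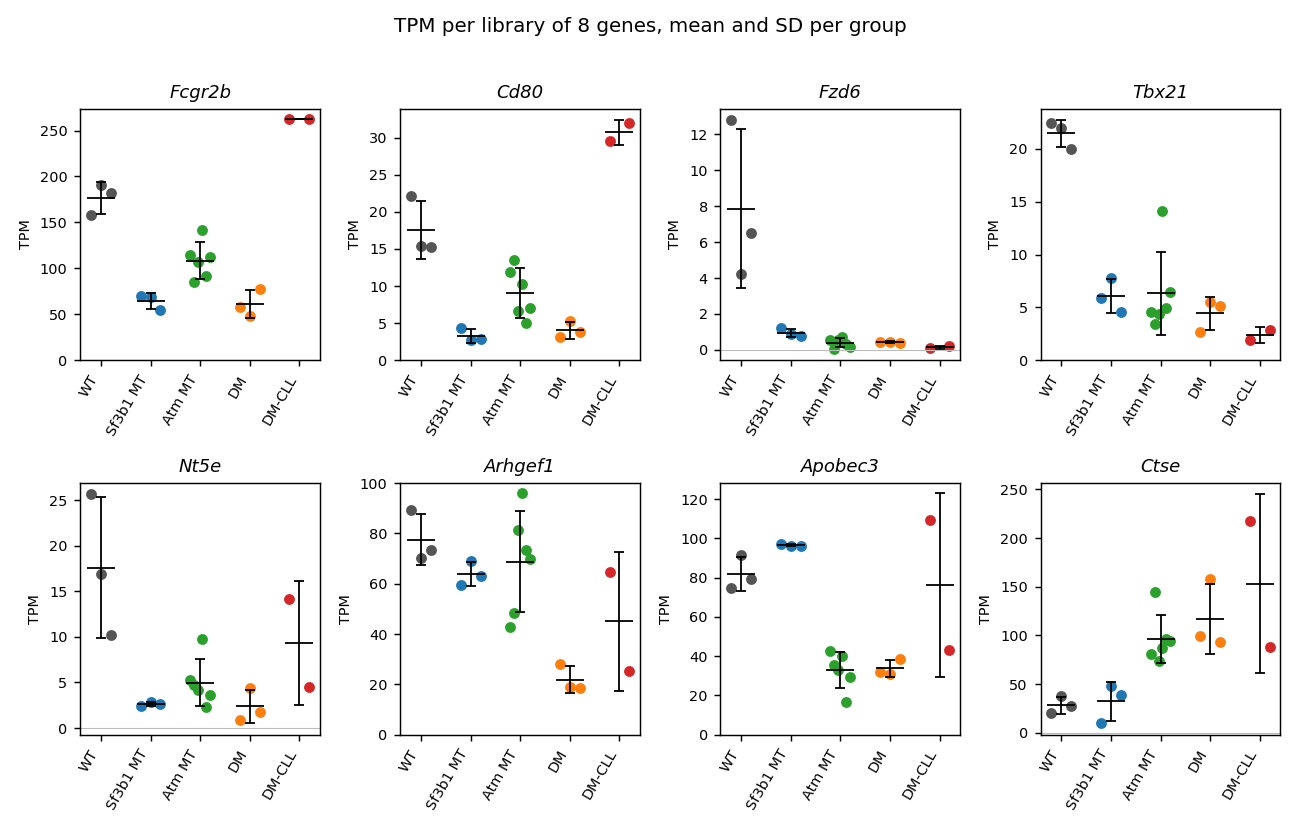
TPM of 8 genes in each library (points), with the mean and SD of each of the 5 groups. Fcgr2b lies at 64.4 TPM in Sf3b1 MT and 61.5 TPM in DM on average, against 177 TPM in WT and 109 TPM in Atm MT.

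The next comparison asked what the Atm lesion alone changes. Tbx21 fell from 21.5 ± 1.29 TPM in WT (SD, n = 3) to 6.33 ± 3.93 in Atm MT (n = 6; log2 −1.74, adjusted p = 0.0148), and Fas, a death receptor and p53 target, from 19.0 ± 6.45 to 5.94 ± 1.58 TPM (adjusted p = 0.0144). Nt5e, the ecto-nucleotidase CD73, fell from 17.6 ± 7.72 to 4.98 ± 2.56 TPM (adjusted p = 0.0493). Fzd6 fell to 0.398 ± 0.257 TPM (log2 −2.57 ± 0.24, adjusted p = 2.04e-04), and Dnm3, a dynamin, from 11.4 ± 8.17 to 1.18 ± 0.611 TPM (adjusted p = 0.00260). The largest falls also included Ramp3, Spon1 and the chemokine Cxcl10. Among the rises, Cyp39a1, an oxysterol hydroxylase, went from 3.88 ± 1.33 to 13.6 ± 3.81 TPM (adjusted p = 0.00817). Ear2, Ctse and Aif1 also rose, Ctse from 28.3 ± 8.72 to 96.1 ± 24.9 TPM. Tbx21 and Fas lost their calls without WT replicate 1 (adjusted p = 0.0899 and 0.119) or WT replicate 2 (adjusted p = 0.0850 and 0.0816). Nt5e lost its call after median-ratio scaling and without WT replicate 1 or 2 or Atm MT replicate 1, 2, 3 or 5 (adjusted p = 0.0579 to 0.282). Ctse passed in 1 of 9 omissions and lost its call after scaling (adjusted p = 0.0525).

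Of the 13 age-associated and memory B-cell genes, Tbx21, Nt5e and Fas fell over all genes and 7 when adjusted over the list alone (median −0.87; adjusted p = 1.11e-05; adjusted p = 0.367 with an estimated correlation). Platelet genes stood lower (median −0.59), with Ppbp falling from 7.60 to 1.19 TPM and Pf4 from 7.95 to 1.49 (adjusted p = 2.44e-04; adjusted p = 0.517 with an estimated correlation). The platelet mean was 0.55 to 1.08 in Atm MT replicates 1 to 4, 1.48 and 1.46 in replicates 5 and 6, and 1.58 to 2.04 in WT. Ppbp did not pass without WT replicate 2 (adjusted p = 0.0516), and Pf4 did not without WT replicate 1, 2 or 3 (adjusted p = 0.0695, 0.129 and 0.131) or Atm MT replicate 1 or 2 (adjusted p = 0.0676 and 0.0571). Monocyte and macrophage markers had a median of 1.83, with 0 passing over all genes and 15 of 19 higher when adjusted over the list alone (adjusted p = 4.21e-12; adjusted p = 0.393 with an estimated correlation). Among its members, the iron exporter Slc40a1 measured 9.77 ± 6.20 TPM in WT and 84.9 ± 63.5 in Atm MT, and Hmox1 25.6 ± 12.7 and 189 ± 140 TPM. The spread came from Atm MT replicates 1 to 4, which held 120 to 241 TPM of C1qa, a macrophage complement gene, against 8.01 to 35.9 TPM in the other 13 libraries. The same 4 libraries held 0.23 to 0.94 TPM of Cd7, against 14.3 to 60.1 TPM elsewhere, C1qa and Cd7 being chosen after their values were seen. Natural killer cell markers were lower in Atm MT (median −0.82, 7 of 11 when adjusted over the list alone; adjusted p = 2.14e-05; adjusted p = 0.587 with an estimated correlation). Without those 4 libraries the macrophage median was 0.31 and that of the natural killer list −0.08, and neither was called. The platelet list was still called, at a median of −0.36, though Ppbp (adjusted p = 0.129) and Pf4 (adjusted p = 0.255) did not pass. The age-associated list was still called, at −0.82.

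In limma, 64 genes passed between Atm MT and WT, 20 rising and 44 falling. After median-ratio scaling 62 passed, 52 of them shared. The count was 19 without WT replicate 1, 24 without WT replicate 2 and 198 without Atm MT replicate 6. Without Atm MT replicates 1 to 4, an alternative chosen after the data were seen, 40 genes passed, 20 of them shared. Ear2, Ctse, Cyp39a1, Aif1, Spon1 and Cxcl10 then lost their calls. Fzd6 and Dnm3 kept theirs in every setting and omission tried. Both were also low in Sf3b1 MT, at 0.947 ± 0.244 and 1.88 ± 0.388 TPM, and only WT was high. These falls are therefore not particular to the Atm lesion, and they rest on the same WT libraries as the other comparisons with WT.

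**Figure D2:**
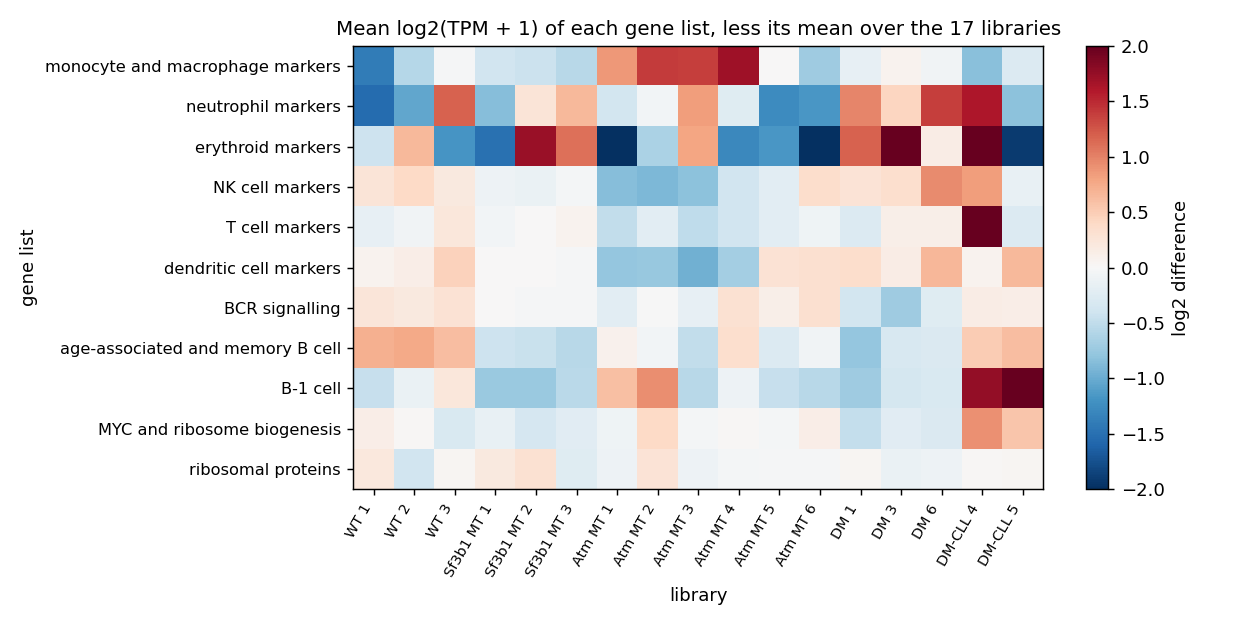
Heat map of 11 gene lists (vertical) in the 17 libraries (horizontal), coloured by mean log2(TPM + 1) less the mean over all libraries, from −2 to 2. Atm MT replicates 1 to 4 have macrophage list means of 4.62 to 5.45 before centring, against 2.36 to 3.83 in the other 13 libraries.

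The question for DM against WT was what both lesions together change before leukaemia. Fcgr2b fell to 61.5 ± 15.1 TPM (log2 −1.53, adjusted p = 0.00324) from 177 ± 16.9 (SD, n = 3 each), and Cd72, another inhibitory B-cell receptor, from 236 ± 26.5 to 90.7 ± 8.04 TPM (adjusted p = 0.0306). Cd80 fell to 4.05 ± 1.12 TPM (adjusted p = 0.0118), Nt5e to 2.36 ± 1.82 TPM (log2 −2.52 ± 0.41, adjusted p = 0.0129) and Tbx21 to 4.45 ± 1.58 TPM (log2 −2.09 ± 0.36, adjusted p = 0.0141). Fzd6 fell to 0.437 ± 0.0404 TPM (log2 −2.51 ± 0.28, adjusted p = 0.00189) and kept its call in every setting and omission. The largest falls also held Hist2h2aa1, Ramp3, Gvin1, Dnm3, Ypel3 and Rcn3. Ctse rose to 117 ± 35.8 TPM (adjusted p = 0.0321) and Glo1, which detoxifies methylglyoxal, from 18.8 ± 1.73 to 34.3 ± 4.12 TPM (adjusted p = 0.0433). Hebp1, Cd14 and Aif1 also rose, Cd14 being the monocyte co-receptor for lipopolysaccharide, from 2.93 ± 1.47 to 9.74 ± 1.05 TPM. Fcgr2b passed in all 6 omissions. Without WT replicate 1 Cd80, Nt5e and Tbx21 did not pass (adjusted p = 0.0613 each), nor did Tbx21 without DM replicate 1 (adjusted p = 0.0601). Ctse and Cd72 passed only without DM replicate 6, and Glo1 and Cd14 in none of the omissions (adjusted p = 0.0555 to 0.189). Hebp1, Aif1, Ramp3 and Ypel3 passed in 1 of 6 omissions each, and Hist2h2aa1 and Gvin1 in 0. Dnm3 passed in 4 and Rcn3 in 5.

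Of 31 genes of B-cell receptor signalling, 7 fell over all genes, 21 fell when adjusted over the list alone and 0 rose (median −0.62, or −0.37 relative to all genes; adjusted p = 5.66e-08; adjusted p = 0.587 with an estimated correlation). Examples are Ptprc, from 177 ± 23.4 to 63.9 ± 21.9 TPM (adjusted p = 0.0400, and 0.0587 to 0.142 when any 1 library was left out), Fcgr2b and Cd72. Of the 13 age-associated and memory B-cell genes, 7 fell over all genes and 8 when adjusted over the list alone, among them Fas and Cd86 (median −1.17, or −0.92 relative to all genes; adjusted p = 2.12e-05; adjusted p = 0.367 with an estimated correlation). The same WT libraries, with means of 4.31 to 4.45 for this list, were the reference for Sf3b1 MT, Atm MT and DM. The lower values in these groups are therefore not independent results. MHC class II genes had 2 of 14 members falling and 7 when adjusted over the list alone (median −0.55, or −0.30 relative to all genes; adjusted p = 0.00181; adjusted p = 0.703 with an estimated correlation). All 15 neutrophil genes had log2 ratios above 0 (median 1.47), with 0 rising over all genes and 3 when adjusted over the list alone (adjusted p = 2.09e-13; adjusted p = 0.436 with an estimated correlation). The neutrophil means were 3.76, 3.22 and 4.17 in DM and 1.24, 1.75 and 3.97 in WT. WT replicate 3 thus lay above DM replicates 1 and 3. All 9 erythroid genes (median 1.61, adjusted p = 3.67e-08) and 17 of 19 macrophage genes (median 0.54, adjusted p = 5.01e-08) also lay above 0. Natural killer (median 0.24, adjusted p = 0.00283) and dendritic cell genes (median 0.25, adjusted p = 0.00154) were called higher too. These 4 lists had adjusted p = 0.517 to 0.703 with an estimated correlation. The erythroid means of DM were 4.95, 6.75 and 3.92, against 3.36, 4.43 and 2.60 in WT, so that WT replicate 2 lay above DM replicate 6, and without DM replicate 3 the median was 0.88, still called. For the macrophage list, WT replicate 3 (3.73) lay above DM replicates 1 (3.59) and 6 (3.69). Of the members of these 4 lists Cd14 alone passed, and the natural killer call was lost without DM replicate 6, at a median of 0.0, and after median-ratio scaling. The T-cell list was called higher with a median of 0.13 and a mean of −0.01 (adjusted p = 0.0106; adjusted p = 0.587 with an estimated correlation), and was not called without DM replicate 3 (median 0.04).

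In limma, 221 genes passed between DM and WT, 15 rising and 206 falling, with a median log2 ratio over all genes of −0.25. After median-ratio scaling 27 passed, 15 rising and 12 falling, with 23 shared, so that the share rising went from 6.8% to 55.6%. Scaling left 1 of the 7 B-cell receptor genes and 1 of the 7 age-associated genes falling. The calls of Ctse, Aif1, Glo1, Fzd6 and Tbx21 (adjusted p = 0.0497) held, and those of Hebp1, Cd14, Hist2h2aa1, Ramp3, Nt5e (adjusted p = 0.0510), Gvin1, Dnm3, Ypel3, Rcn3 and Cd80 (adjusted p = 0.0604) did not. The count was 10 without WT replicate 1, 70 without WT replicate 2, 115 without WT replicate 3, 41 without DM replicate 1, 38 without DM replicate 3, 139 without Sf3b1 MT replicate 1 and 128 without Sf3b1 MT replicate 3.

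To isolate the Sf3b1 mutation in cells with the Atm lesion, DM was compared with Atm MT. Arhgef1, an activator of RhoA in lymphocytes (chromosome 7, 24902912 to 24926594), fell from 68.7 ± 20.1 TPM in Atm MT (SD, n = 6) to 21.8 ± 5.36 in DM (n = 3; log2 −1.58 ± 0.22, adjusted p = 0.0160). It kept its call in all 9 settings and all 9 omissions. Tlr1, a receptor for bacterial lipopeptides, fell from 35.4 ± 11.3 to 11.9 ± 3.0 TPM (log2 −1.46, adjusted p = 0.0160). Eif4a2, Nid1 and Zfp605 also fell, and the call of Eif4a2 was lost after median-ratio scaling (adjusted p = 0.0545). The largest rises were red-cell genes. Car1, an erythroid carbonic anhydrase, measured 3.89 ± 3.45 TPM in Atm MT and 132 ± 140 in DM (log2 4.57, adjusted p = 0.0201), with DM replicates at 54.8, 293 and 46.9 TPM, and Aqp1, Cldn13, Rhd and Car2 rose with it. Without DM replicate 1 neither Tlr1 nor Car1 passed (adjusted p = 0.0621 each), nor did they without DM replicate 3 (adjusted p = 0.102 and 0.137), and Car1 did not without Atm MT replicate 4 (adjusted p = 0.0537).

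Of 9 erythroid genes 6 rose, over all genes and when adjusted over the list alone (median 2.69; adjusted p = 2.81e-11; adjusted p = 0.393 with an estimated correlation). The neutrophil granule genes Mpo, Elane and Prtn3 rose, Mpo from 0.330 ± 0.456 to 8.89 ± 4.39 TPM (list median 1.25; adjusted p = 1.70e-11; adjusted p = 0.517 with an estimated correlation). The list means of Atm MT and DM overlapped. Atm MT replicate 3 lay above DM replicate 6 for the erythroid list (4.57 against 3.92). It lay above DM replicate 3 for the neutrophil list (3.63 against 3.22). The cytotoxic genes Klrd1, Nkg7 and Gzma rose, and 8 of 11 natural killer genes did when adjusted over the list alone (median 0.73; adjusted p = 2.59e-11; adjusted p = 0.367 with an estimated correlation). The mean of that list was 0.25 to 0.76 in Atm MT replicates 1 to 4, 0.93 and 1.49 in replicates 5 and 6, and 1.42 to 2.09 in DM. Without replicates 1 to 4 its median was 0.31, still called, and Klrd1 (adjusted p = 0.324), Nkg7 (adjusted p = 0.0661) and Gzma (adjusted p = 0.0782) did not pass. Klrd1 (adjusted p = 0.0601 to 0.186) and Gzma (adjusted p = 0.0514 to 0.169) also did not pass when any 1 of Atm MT replicates 1 to 4 or DM replicates 1, 3 and 6 was left out. Nkg7 did not without Atm MT replicate 4 (adjusted p = 0.0553), DM replicate 1 (adjusted p = 0.0590) or DM replicate 3 (adjusted p = 0.143). Other lists also set Atm MT replicates 1 to 4 apart. Dendritic means were 1.31 to 1.58 there, 2.56 and 2.59 in replicates 5 and 6, and 2.41 to 2.93 in DM. Platelet means were 0.55 to 1.08, then 1.48 and 1.46, and 1.6 to 1.7 in DM. Macrophage means were 4.62 to 5.45, then 3.77 and 3.04, and 3.59 to 3.83 in DM. Of 31 genes of B-cell receptor signalling, 9 fell over all genes and 17 when adjusted over the list alone (median −0.48, or −0.28 relative to all genes; adjusted p = 5.91e-05; adjusted p = 0.703 with an estimated correlation). Examples are Malt1, from 62.2 ± 15.2 to 30.4 ± 9.31 TPM (adjusted p = 0.0277), Bank1 (adjusted p = 0.0400) and Ptprc (adjusted p = 0.0497), all of which lost their calls without Atm MT replicate 4 (adjusted p = 0.0626, 0.0832 and 0.0990), DM replicate 1 (adjusted p = 0.0621, 0.0677 and 0.0758) or DM replicate 3 (adjusted p = 0.175, 0.223 and 0.251). Mpo (adjusted p = 0.0621) also lost its call without DM replicate 1. Of 28 genes of MYC and ribosome biogenesis, 3 fell and 12 when adjusted over the list alone (median −0.30; adjusted p = 0.0227; adjusted p = 0.882 with an estimated correlation), and this call was lost after scaling, where the median was −0.04, and without Atm MT replicate 2 (−0.24), DM replicate 1 (−0.16) or DM replicate 6 (−0.35).

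In limma, 599 genes passed between DM and Atm MT, 152 rising and 447 falling, at a median over all genes of −0.21. After median-ratio scaling 386 passed, 275 rising and 111 falling, with 254 shared, so that the share rising went from 25.4% to 71.2%, and 1 of the 9 B-cell receptor genes still fell. The count was 361 without Atm MT replicate 2, 18 without Atm MT replicate 4, 7 without DM replicate 1, 9 without DM replicate 3, 293 without WT replicate 1, 283 without WT replicate 2 and 266 without Sf3b1 MT replicate 3, since all libraries share 1 estimate of spread. Without Atm MT replicates 1 to 4 it was 27, with 16 shared.

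To isolate the Atm lesion on an Sf3b1-mutant background, DM was compared with Sf3b1 MT. Apobec3, a cytidine deaminase that restricts retroviruses (chromosome 15, 79891659 to 79915906), fell from 96.5 ± 0.566 TPM in Sf3b1 MT to 33.7 ± 4.13 in DM (SD, n = 3 each; log2 −1.50, adjusted p = 0.0319), and measured 81.9 ± 8.74 in WT and 32.9 ± 9.34 in Atm MT (n = 6). Arhgef1 fell from 63.8 ± 4.83 to 21.8 ± 5.36 TPM (log2 −1.53 ± 0.26, adjusted p = 0.0319). Hcfc1r1 fell from 33.6 ± 8.0 to 11.1 ± 3.41 TPM (adjusted p = 0.0288), Ptp4a3, a phosphatase, from 89.6 ± 17.8 to 31.7 ± 6.63 TPM (adjusted p = 0.0319), and Sh3bgrl3 from 894 ± 183 to 422 ± 34.1 TPM. The genes that rose were Gm12191, Col6a4, Gprc5b and Psca, singled out after their values were seen. After median-ratio scaling Hcfc1r1 (adjusted p = 0.0318) and Ptp4a3 (adjusted p = 0.0386) kept their calls, whereas Arhgef1 (adjusted p = 0.0557), Apobec3 (adjusted p = 0.125) and Sh3bgrl3 (adjusted p = 0.146) lost theirs. When 1 library was left out, Hcfc1r1 passed only without Sf3b1 MT replicate 3 or DM replicate 1, Sh3bgrl3 only without Sf3b1 MT replicate 3, and the other named genes in none of 6 omissions (adjusted p = 0.0602 to 0.201).

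All 14 follicular B-cell genes had log2 ratios below 0 in DM (median −0.64), with 0 passing over all genes and 5 falling when adjusted over the list alone (adjusted p = 3.80e-04; adjusted p = 0.703 with an estimated correlation). Its member Fcer2a, which encodes CD23, measured 268 ± 21.9 in Sf3b1 MT and 132 ± 45.8 TPM in DM. Genes of B-cell receptor signalling had a median of −0.43, or −0.33 relative to all genes, with 0 passing over all genes and 7 falling when adjusted over the list alone (adjusted p = 4.03e-07; adjusted p = 0.587 with an estimated correlation). All 24 mitosis genes had log2 ratios above 0 (median 0.47), none of which passed in limma over all genes or over the list alone (adjusted p = 3.10e-06; adjusted p = 0.754 with an estimated correlation), and without DM replicate 3 the list was not called, at a median of 0.02. Lists of other cells were called in the same comparison, with medians of 0.92 for erythroid (9 of 9 genes above 0, adjusted p = 6.71e-04), 0.85 for neutrophil (adjusted p = 7.15e-08), 0.64 for natural killer (adjusted p = 3.58e-06), 0.41 for macrophage (adjusted p = 2.13e-04), 0.38 for dendritic (adjusted p = 1.85e-04) and −0.68 for platelet genes (adjusted p = 3.80e-04). These had adjusted p = 0.517 to 0.703 with an estimated correlation, and 0 of their members passed over all genes in limma. DM replicate 3 had the highest erythroid mean of the DM libraries (6.75, against 4.95 and 3.92), and the erythroid call was lost without it (0.15) or without Sf3b1 MT replicate 1 (0.12), and after median-ratio scaling. Mki67, the proliferation marker Ki-67, measured 6.65 ± 2.28 TPM in Sf3b1 MT and 13.1 ± 9.44 in DM. In limma, 12 genes passed, 4 rising and 8 falling, with a median over all genes of −0.11. After median-ratio scaling 16 passed, 10 rising and 6 falling, with 8 shared, the share rising going from 33.3% to 62.5%. The count was 0 without Sf3b1 MT replicate 1 (772 at an unadjusted p below 0.05), replicate 2 (683) or DM replicate 3 (795), 1 without DM replicate 6, 7 without WT replicate 3, and 2 without Sf3b1 MT replicate 3 or DM replicate 1.

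The interaction of the lesions asked whether the effect of one depends on the other. In limma no gene passed (0 of 9898, with 546 at an unadjusted p below 0.05), before or after median-ratio scaling (696 at an unadjusted p below 0.05). The named gene with the smallest adjusted p was Fzd6 (log2 2.14 ± 0.37, adjusted p = 0.365), followed by Cst7, a cystatin of cytotoxic cells (1.59, adjusted p = 0.378), and Hoxa7 (1.37, adjusted p = 0.483). Fzd6 was low in each mutant group, at 0.947 ± 0.244 TPM in Sf3b1 MT, 0.398 ± 0.257 in Atm MT and 0.437 ± 0.0404 in DM, against 7.85 ± 4.43 in WT (SD, n = 3, 6, 3 and 3). The count was 1 without WT replicate 2, WT replicate 3 or Atm MT replicate 6. Of the fixed lists, 17 were called, 13 higher and 4 lower, with adjusted p = 0.367 to 0.917 with an estimated correlation. Across genes, which are not independent replicates, the Sf3b1 effect without the Atm lesion and with it had a Spearman correlation of 0.419 (jackknife SE over libraries 0.145) and a Pearson correlation of 0.356. It was 0.286 to 0.465 when 1 library was left out and 0.332 without Atm MT replicates 1 to 4. The Atm effect without and with the Sf3b1 lesion had a Spearman correlation of 0.235. It was 0.109 to 0.329 when 1 library was left out, lowest without WT replicate 3 (0.109) and Sf3b1 MT replicate 2 (0.131) and highest without WT replicate 2 (0.317) and DM replicate 3 (0.329). It was 0.044 without Atm MT replicates 1 to 4 and 0.409 with the replicate block.

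**Figure D3:**
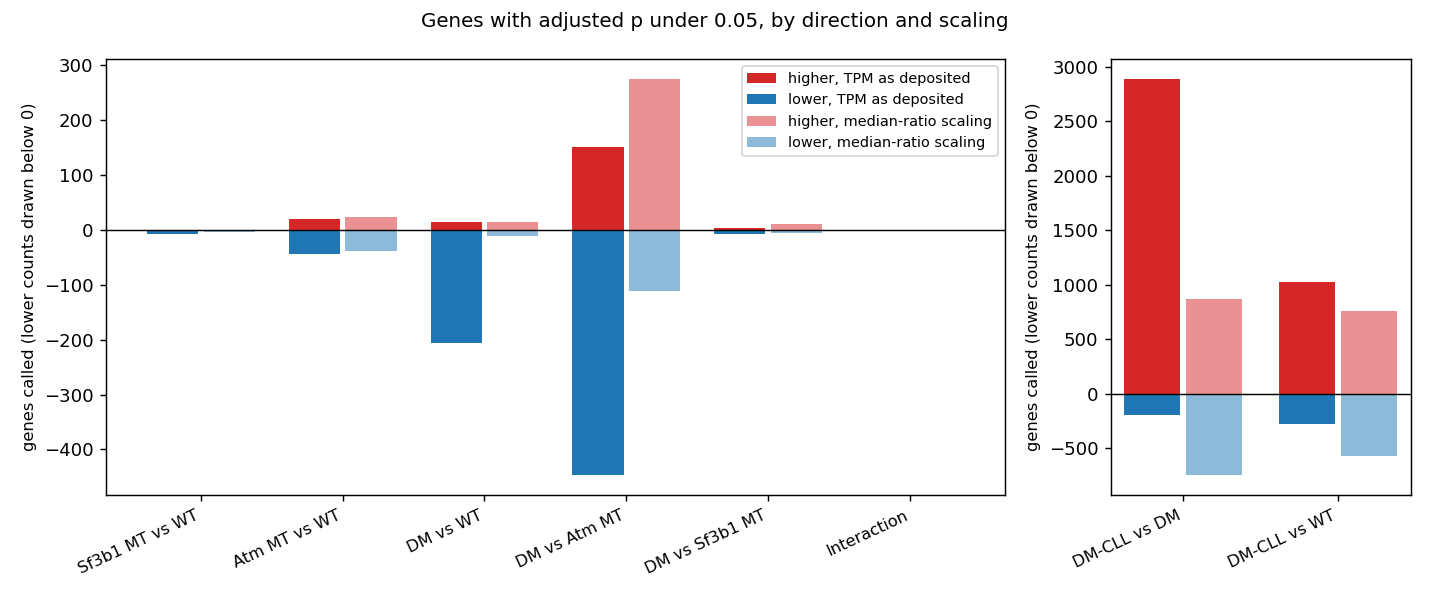
Bars give the number of genes that rose and fell in each comparison, for TPM as deposited and after median-ratio scaling, with the DM-CLL comparisons on their own axis. DM against WT has 206 falls as deposited and 12 after scaling, and DM-CLL against DM has 2889 rises as deposited and 873 after scaling.

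What separates leukaemic from non-leukaemic double-mutant cells was the question for DM-CLL against DM. Cd5, a surface marker that CLL cells share with B-1a cells, rose from 2.0 ± 0.977 TPM in DM (SD, n = 3) to 25.8 ± 7.11 in DM-CLL (n = 2; log2 3.19 ± 0.62, adjusted p = 0.00144). Ctla4, an inhibitory receptor of the CD28 family, rose from 4.45 ± 1.42 to 181 ± 40.5 TPM (log2 5.08, adjusted p = 1.91e-05). Zbtb32, a transcriptional repressor, rose from 5.23 ± 3.37 to 175 ± 3.41 TPM (log2 4.97, adjusted p = 0.0010), and Il5ra, the interleukin-5 receptor of B-1 cells, from 3.17 ± 0.709 to 69.0 ± 6.45 TPM (log2 4.08, adjusted p = 9.85e-05). The largest rises were Cyp11a1, the first enzyme of steroid synthesis, from 3.25 ± 5.31 to 144 ± 88.5 TPM (log2 5.74 ± 0.77), and the actin-binding Avil, from 1.11 ± 1.63 to 92.1 ± 38.2 TPM. Vars, Krt18, Gnb3, Gng13, Snora73a and Fabp7 complete that set. Among the falls, Slpi, a secreted protease inhibitor, went from 353 ± 125 to 24.5 ± 12.2 TPM (log2 −3.83, adjusted p = 2.03e-04), Tnfrsf17, the plasma-cell receptor BCMA, from 19.6 ± 5.06 to 1.20 ± 0.276 TPM, and Fcer2a from 132 ± 45.8 to 24.8 ± 9.04 TPM (log2 −2.34, adjusted p = 0.00138). Prg2, Chst1, Mdfic, Myl4, Crisp3, Ifitm1 and the complement receptor Cr2 also fell. All 20 genes kept their calls after median-ratio scaling, and Vars (adjusted p = 0.0594), Snora73a (adjusted p = 0.192), Mdfic (adjusted p = 0.119), Ifitm1 (adjusted p = 0.0642) and Cr2 (adjusted p = 0.0734) lost theirs without DM-CLL replicate 4. Snora73a also lost its call without DM replicate 1 (adjusted p = 0.0538) or DM replicate 3 (adjusted p = 0.0520).

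Of 17 genes of B-1 cells, 14 rose over all genes, 16 when adjusted over the list alone and 0 fell (median 2.42, or 1.99 relative to all genes; adjusted p = 3.30e-05; adjusted p = 0.587 with an estimated correlation), and 9 rose after scaling. Of 28 genes of MYC and ribosome biogenesis, 23 rose, 26 when adjusted over the list alone (median 0.97, or 0.54 relative to all genes; adjusted p = 3.07e-06; adjusted p = 0.616 with an estimated correlation), and 7 rose after scaling. Myc, which lies on chromosome 15, rose from 12.4 ± 5.81 to 42.4 ± 5.86 TPM (log2 1.80, adjusted p = 0.00242), and the nucleolar genes Wdr43 and Gnl3 by 2.13 and 1.81. Of 12 plasma-cell genes 5 fell and 1 rose, 6 and 1 when adjusted over the list alone (median −0.80, or −1.23 relative to all genes; adjusted p = 5.66e-08; adjusted p = 0.367 with an estimated correlation), among them Tnfrsf17, Sdc1 (−2.19) and Xbp1 (−1.43). Of 14 follicular genes 5 fell and 2 rose, 5 and 3 when adjusted over the list alone (median −0.30, or −0.73 relative to all genes; adjusted p = 2.06e-04; adjusted p = 0.616 with an estimated correlation), with Ccr6 and Ccr7 both at −2.26, calls lost without DM-CLL replicate 4 (adjusted p = 0.108 and 0.0785). Of 23 spliceosome genes 12 rose, 16 when adjusted over the list alone, Srsf2 by 1.28 and Phf5a by 1.15 (median 0.65, or 0.22 relative to all genes; adjusted p = 0.0209; adjusted p = 0.863 with an estimated correlation). That list call was lost after scaling, where 3 rose and 1 fell, and without DM replicate 6 (0.65) or DM-CLL replicate 4 (0.48), where Phf5a did not pass (adjusted p = 0.0797). Ribosomal protein genes were called lower at a median of 0.02, or −0.52 after scaling (adjusted p = 2.75e-05; adjusted p = 0.882 with an estimated correlation).

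Among B-cell genes chosen in advance, Ms4a1, which encodes CD20, rose from 322 ± 66.7 to 675 ± 27.8 TPM (log2 1.09, adjusted p = 0.00320) and lost its call after scaling (0.55, adjusted p = 0.0722). Bcl2, which blocks apoptosis, rose from 11.1 ± 3.77 to 29.8 ± 12 TPM (log2 1.35, adjusted p = 0.00338), a call lost without DM-CLL replicate 5 (0.94, adjusted p = 0.0555). Lef1, at 0.387 ± 0.168 and 1.78 ± 0.297 TPM, passed with adjusted p = 0.0406 and lost its call after scaling (adjusted p = 0.150) and in each of the 5 omissions: DM replicates 1, 3 and 6 (adjusted p = 0.0600, 0.0996 and 0.0697) and DM-CLL replicates 4 and 5 (adjusted p = 0.191 and 0.0783). Cd79a (0.22, adjusted p = 0.409) and Cd79b (0.45, adjusted p = 0.130) did not pass, and their ratios were −0.32 and −0.08 after scaling. Lists of other cells were called lower in DM-CLL, with medians of −0.66 for macrophage (adjusted p = 8.86e-06), −0.77 for neutrophil (adjusted p = 2.46e-05), −0.22 for natural killer (adjusted p = 0.00402), −0.22 for platelet (adjusted p = 0.00268), −0.41 for dendritic (adjusted p = 0.0109) and −0.55 for erythroid genes (adjusted p = 0.0128). The immediate early genes, which respond to handling, were at −0.30 (adjusted p = 9.10e-07). These lists had adjusted p = 0.587 to 0.831 with an estimated correlation. Without DM-CLL replicate 5 the neutrophil (0.28) and natural killer (−0.06) calls were lost and the erythroid list turned (2.26), which was also not called without DM replicate 3 (0.18). Without DM-CLL replicate 4 the dendritic (−0.22) and platelet (−0.02) calls were lost. After median-ratio scaling only the immediate early list was still called. The dendritic list had a mean of −0.03, with 2 of its 12 members rising. Markers of other cells differed between the leukaemic libraries. The T-cell gene Cd3e measured 11.9 TPM in DM-CLL replicate 4 and 0.39 in replicate 5, and the globin gene Hba-a1 measured 7274 and 9.41 TPM, a pair chosen after their values were seen. In limma, 3084 genes passed, 2889 rising and 195 falling, at a median over all genes of 0.43. After median-ratio scaling 1622 passed, 873 rising and 749 falling, with 1068 shared, so that the share rising went from 93.7% to 53.8%. Without DM-CLL replicate 4 the count was 1504.

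**Figure D4:**
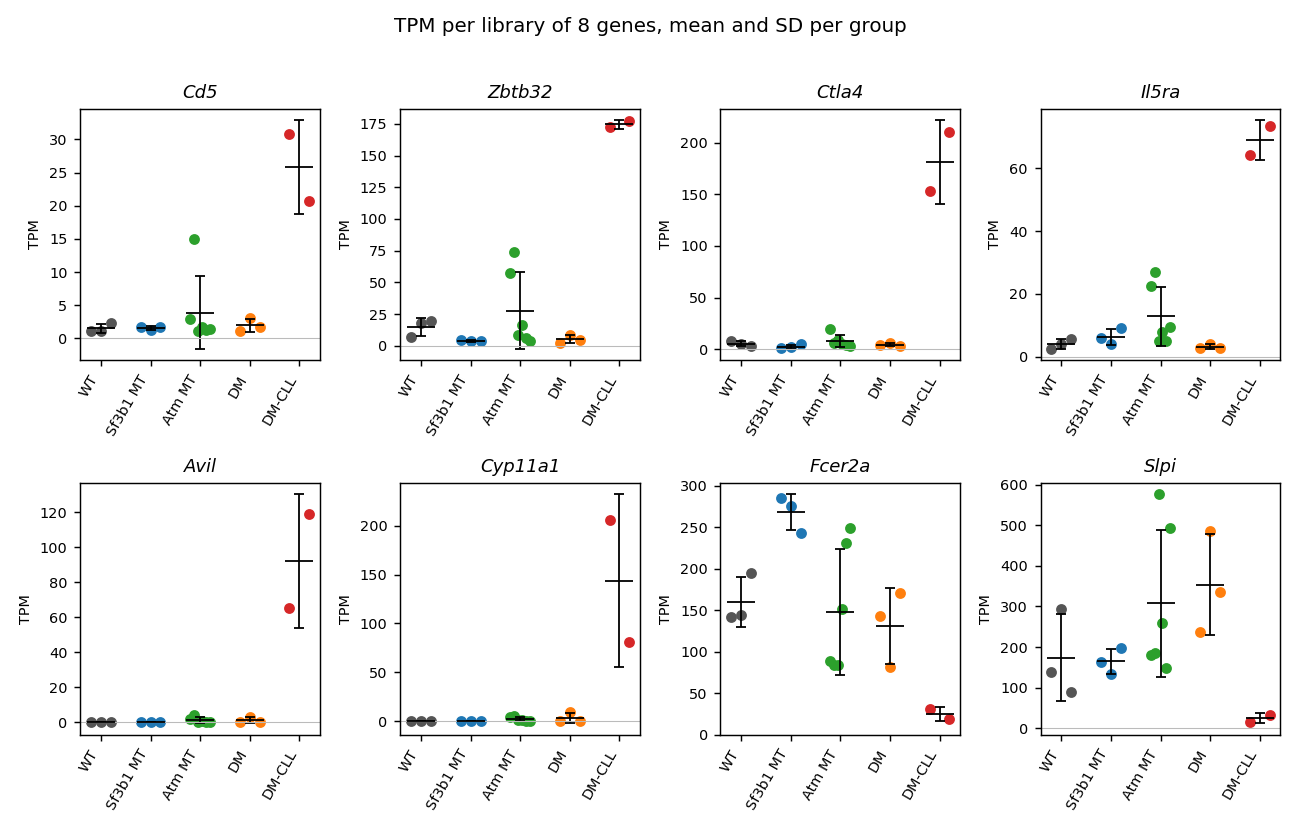
TPM of 8 genes in each library (points), with the mean and SD of each of the 5 groups. Cd5 averages 25.8 TPM in DM-CLL against 2.0 TPM in DM, and Slpi 24.5 TPM against 353 TPM.

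DM-CLL was also set against WT, to compare leukaemic with normal B cells. Cd5 rose from 1.54 ± 0.679 TPM in WT (SD, n = 3) to 25.8 ± 7.11 in DM-CLL (n = 2; log2 3.41, adjusted p = 0.00150), and Ctla4, Il5ra and Zbtb32 rose by 4.89, 3.83 and 3.59. Zbtb32 did not pass without WT replicate 1, DM-CLL replicate 4 or DM-CLL replicate 5 (adjusted p = 0.0584, 0.0862 and 0.0630). Cyp11a1 rose from 0.343 ± 0.10 TPM to 144 ± 88.5 (log2 6.60, adjusted p = 4.05e-05), followed by Avil, Krt18, Gnb3 and Gng13. Ccr6, a homing receptor of follicular and memory B cells, fell from 19.2 ± 0.630 to 1.61 ± 1.85 TPM (log2 −3.16, adjusted p = 7.64e-04). Chst1, Eps8l1, Ramp3 and Spon1 also had among the largest falls. Eps8l1 lost its call without WT replicate 1, WT replicate 3 or either DM-CLL library. Cd22, an inhibitory co-receptor, fell from 359 ± 77.9 to 92.9 ± 8.12 TPM (log2 −1.92, adjusted p = 4.09e-04), and Cd40, the receptor for T-cell help, from 63.8 ± 11.6 to 18.1 ± 2.83 TPM (log2 −1.75, adjusted p = 0.00150).

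Of 17 B-1 genes, 12 rose and 0 fell, 13 rising when adjusted over the list alone, and all 17 had ratios above 0 (median 1.46, or 1.27 relative to all genes; adjusted p = 5.30e-07; adjusted p = 0.517 with an estimated correlation). Of 28 genes of MYC and ribosome biogenesis 16 rose, 22 when adjusted over the list alone (median 0.75, or 0.56 relative to all genes; adjusted p = 5.30e-07; adjusted p = 0.587 with an estimated correlation). After scaling 10 and 9 genes of these lists rose. Of 14 follicular genes 5 fell over all genes, with a median of −0.67, or −0.86 relative to all genes (adjusted p = 1.43e-06; adjusted p = 0.517 with an estimated correlation). Of 14 MHC class II genes 5 fell, and 8 fell and 1 rose when adjusted over the list alone (median −0.61; adjusted p = 1.09e-05; adjusted p = 0.587 with an estimated correlation). The immediate early genes, which respond to handling, were called lower too, with 3 of 21 falling (median −0.53; adjusted p = 2.06e-04; adjusted p = 0.703 with an estimated correlation), a call lost without DM-CLL replicate 4 (−0.37). Cd79a (−0.40, adjusted p = 0.206), Cd79b (−0.28, adjusted p = 0.457), Ms4a1 (0.69, adjusted p = 0.0678), Bcl2 (0.57, adjusted p = 0.230) and Lef1 (0.69, adjusted p = 0.226) did not pass. After median-ratio scaling Cd79a (−0.60, adjusted p = 0.0458) did. In limma, 1299 genes passed, 1021 rising and 278 falling, at a median over all genes of 0.19. After scaling 1336 passed, 759 rising and 577 falling, with 1033 shared, the share rising going from 78.6% to 56.8%. Without DM-CLL replicate 4 the count was 696.

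Expression was also summarised by chromosome, over 6403 genes with a known position and a mean of at least 5 TPM in the non-leukaemic libraries. Genes of chromosome 15, which carries Myc, Krt18, Fzd6, Ptp4a3 and Apobec3, had a median log2 ratio to the non-leukaemic libraries, relative to all genes of the library, of 0.614 in DM-CLL replicate 4 and 0.640 in DM-CLL replicate 5. Of its 276 genes, 87.0% and 88.0% lay above 0. Split by position into 3 parts of 92 genes each, the medians were 0.571, 0.704 and 0.591 in replicate 4 and 0.755, 0.551 and 0.586 in replicate 5. Chromosome 17 had medians of 0.211 and 0.295 over 349 genes. The 285 autosome values of the 15 other libraries ran from −0.187 to 0.16, and the chromosome 15 values of Atm MT replicates 1 and 2 were 0.16 and 0.153. Chromosomes were singled out after their values were seen.

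**Figure D5:**
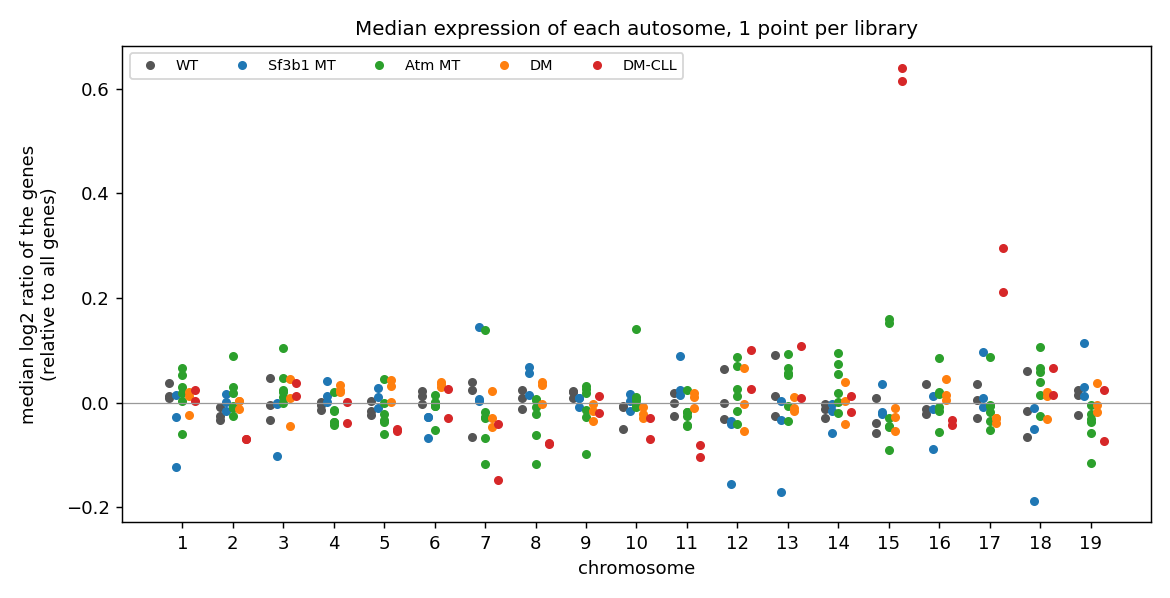
Median log2 ratio of the genes of each autosome (horizontal) in each of the 17 libraries (points), against the non-leukaemic libraries. Chromosome 15 stands at 0.614 and 0.640 in the DM-CLL libraries, against at most 0.16 on any autosome of the other 15.

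Over the 8 comparisons, 272 tests of lists gave 114 calls at the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.347 and 24 tests had an unadjusted p below 0.05. Median-ratio scaling lost 33 of the 114 calls. The lists of p53 targets, DNA repair, Notch and Wnt signalling, human CLL markers, marginal zone B cells and genes with aberrant splicing in SF3B1-mutant cells were called in no comparison. Their smallest adjusted p were 0.0865, 0.148, 0.340, 0.249, 0.0789 and 0.280 at the preset correlation. The test sets a list against all other genes, so a list that is not called can still differ between groups. Human CLL markers had means of 4.64 and 4.16 in DM-CLL, against 3.15 to 3.82 in the other 15 libraries. Gene-level TPM do not measure splicing itself.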

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

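The tests of a minor population, of RNA carried over, of the unlisted share of the TPM and of other splits of the samples were chosen after the results they concern were seen. So were the test of GC content and transcript length on chromosome 15 and the fit without ribosomal protein genes. Of 74 values tested in the 6 Atm MT libraries, 9 had 1 library far from the other 5, by a gap that was, as a share of the group's range, above Dixon's 95% critical value. For independent, normally distributed values chance gives about 1 in 20 such results, or 3.7 of 74. Some genes had medians near 0 and genes of 1 library can vary together, so 3.7 is only a rough guide. In Atm MT replicate 1, Fabp7 measured 26.04 TPM (median of the others 0.78), Prg2 13.47 (64.94) and Mdfic 6.18 (10.97). In replicate 2, Cd5 measured 15 TPM (1.42) and Lef1 1.98 (0.30). In replicate 3, Hist2h2aa1 measured 9.09 TPM (0.60) and Cdk14 1.75 (2.85). Ramp3 measured 4.13 TPM in replicate 4 (0.30) and Gvin1 84.19 TPM in replicate 6 (23.6).

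The interaction of the lesions was called for 17 gene lists at the preset correlation, whereas none was called with an estimated correlation (adjusted p = 0.367 to 0.917). Lists of other cell types stood out, with medians of 1.35 for natural killer (adjusted p = 2.18e-13), 1.06 for dendritic (adjusted p = 7.51e-09), 2.0 for erythroid (adjusted p = 2.21e-05), 0.87 for neutrophil (adjusted p = 4.44e-05) and 0.17 for T-cell markers (adjusted p = 0.0104), and −1.43 for macrophage markers (adjusted p = 0.0152). Lists of B-cell states were at 1.16 for age-associated and memory cells (adjusted p = 3.04e-06), 0.50 for plasma cells (adjusted p = 2.83e-04) and −0.30 for B-cell receptor signalling (adjusted p = 0.00969). Growth lists were at 0.82 for mitosis, where 24 of 24 genes lay above 0 (adjusted p = 3.37e-07), 0.48 for DNA replication (adjusted p = 5.13e-05), −0.21 for MYC and ribosome biogenesis (adjusted p = 0.0398) and −0.21 for ribosomal proteins (adjusted p = 0.00595). The remaining lists were at 0.59 for the unfolded protein response (adjusted p = 5.67e-07), 0.53 for senescence (adjusted p = 4.07e-04), 0.26 for the BCL2 family (adjusted p = 0.0167) and 0.20 for NF-kB targets (adjusted p = 0.0176). Leaving out 1 library ended 9 of these calls, with the median then given in parentheses. They were the BCL2 family without WT replicate 1 (0.11) or DM replicate 1 (0.27), B-cell receptor signalling and DNA replication without DM replicate 3 (−0.13 and 0.02), NF-kB targets without WT replicate 1 (0.13), Atm MT replicate 2 (0.08) or DM replicate 1 (−0.04), T-cell markers without WT replicate 3 (0.12) or DM replicate 3 (0.14), and neutrophil markers without WT replicate 3 (0.0). Macrophage markers lost theirs without WT replicate 1 (−0.86), Atm MT replicate 1 (−1.40), Atm MT replicate 3 (−1.30) or DM replicate 6 (−1.57), and the MYC and ribosomal protein lists each in at least 5 omissions (−0.27 to −0.02). Without Atm MT replicates 1 to 4 the macrophage interaction reversed, at a median of 0.10 (adjusted p = 0.0426). The dendritic and natural killer interactions also rest in part on these replicates. Dendritic means were 1.31 to 1.58 in them, against 2.56 and 2.59 in Atm MT replicates 5 and 6. Natural killer means were 0.25 to 0.76, against 0.93 and 1.49.

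The first pattern weighed is the raised expression of chromosome 15 in both DM-CLL libraries. A trend with GC content and transcript length is argued against as the whole cause, because the lower of the DM-CLL medians was 0.633 after that trend was removed, and the highest value of the other libraries after the same correction was 0.187. A gain of the whole chromosome in the leukaemic cells predicted a median of 0.3 to 0.8, above every autosome of the other libraries, with over 65% of its genes above the median of all genes. The lower value of 0.614 lay inside that range, as did each part of the chromosome by position, and 87.0% and 88.0% of its genes lay above that median. Chromosome 17 lay below that range at 0.211 and 0.295, but after the same correction its medians were 0.248 and 0.374, the latter inside it. Before correction 63.9% and 71.6% of its genes lay above the median of all genes. Its 3 parts by position were then at 0.223, 0.0 and 0.3 in replicate 4 and 0.288, 0.134 and 0.41 in replicate 5. The first and middle parts were below that range in both, unlike any part of chromosome 15. Whether part of chromosome 17 is gained was not tested. DNA copy number was not measured, so a gain of chromosome 15 is consistent with these values and remains a hypothesis.

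The second pattern is that 811 genes called higher in DM-CLL against WT, outside chromosome 15, also stood higher in Atm MT replicates 1 and 2, with median log2 ratios of 0.399 and 0.419, against 0.244 in DM replicate 3 and −0.035 to 0.188 in the other libraries. A minor population resembling the DM-CLL cells may be present in both, since the lower of their medians exceeded the next highest library by 0.155, though the test was run on the libraries in which the pattern had been noticed. Carry-over of RNA from the DM-CLL libraries would add the same share of every transcript. Of 42 genes most raised in DM-CLL against WT, 9.5% stayed below a twentieth of the lower DM-CLL level in replicate 1 and 19.0% in replicate 2, while 54.8% and 57.1% lay above 20% of it (mean of WT taken off), so the values show unequal shares without excluding a part of it, and this cannot be told apart from a related population. Icos, at 0.33 and 0.22 TPM against 9.59 and 11.7 in DM-CLL, and Zbtb32, at 57.1 and 74.2 against 172 and 177, show the spread.

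The third pattern is that 93.7% of the genes called between DM-CLL and DM were higher in DM-CLL. A larger unlisted share of the TPM in DM is argued against as the whole cause, because 79.7% were still higher once the listed genes were rescaled to a common total, with the same 9898 genes tested. With ribosomal protein genes also out and the rest rescaled, which changed the genes tested as well, 57.5% were higher (863 of 1502), near the 53.8% after median-ratio scaling, so a larger ribosomal protein share in DM may account for much of the imbalance together with the unlisted share, which that rescaling also removes. Ribosomal protein genes took 42.6% to 47.1% of the listed TPM in DM and 34.4% and 38.3% in DM-CLL. Whether that share is biological was not tested.

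Other splits of the same libraries into groups of the same sizes were counted. For Sf3b1 MT against WT (7 genes; highest other split 0), DM against WT (221; 0) and DM against Sf3b1 MT (12; 1), the real split alone reached its count, 1 of 10, and 10 splits are too few for a share below 0.05. For Atm MT against WT, 3 of 84 splits gave at least the real 64 genes, a share below 0.05. Another split, with Atm MT replicates 1, 2 and 3 in place of WT, gave 574. For DM against Atm MT, 2 of 84 splits gave at least the real 599, also a share below 0.05. The split that puts Atm MT replicates 4, 5 and 6 in place of DM, with replicates 1, 2 and 3 beside the DM libraries, gave 1341. Splits with far more genes than the real one point to a structure within the Atm MT libraries. The libraries are then not exchangeable, so these shares neither exclude chance nor tie the counts to genotype. For the interaction, 100 of 100 splits drawn reached the real count of 0 (highest other 7), so chance is not excluded.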

How the results depend on the processing

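Named genes that had passed kept their direction in all 2516 repeats under other settings, 1874 still passing and 642 not. The kept direction is in part fixed by the choice of genes. Among the largest rises and falls the groups did not overlap, so leaving out 1 library could not turn the direction. Called lists kept their call in 1629 of 1894 repeats, lost it in 253 and reversed in 12. Fits without Atm MT replicates 1 to 4, with Xist as covariate, without ribosomal protein genes and with the whole table rescaled were chosen after the data were seen. Where no construction is named, the cause was not tested. Counts are of genes that passed, in limma. Between Sf3b1 MT and WT (7) there were 3 with a pseudocount of 0.1, 17 without a filter, 3 after median-ratio scaling, 4 with immunoglobulin genes out and the table rescaled, 149 with library weights, 4 with the replicate block, 0 with only these groups fitted, which has fewer samples (1397 at an unadjusted p below 0.05), and 0 with Xist as covariate (920). Between Atm MT and WT (64) there were 234 with weights, 303 with the block, 26 with only these groups, 97 with Xist and 40 without replicates 1 to 4. The setting with immunoglobulin genes out removed 2 genes and also rescaled every library, so its counts cannot be credited to those genes. Between DM and WT (221) there were 27 after scaling, 53 with immunoglobulin genes out and the table rescaled, 1933 with weights, 1131 with the block and 35 with only these groups. Between DM and Atm MT (599) there were 168 without a filter, 386 after scaling, 93 with immunoglobulin genes out and the table rescaled, 2173 with weights, 57 with only these groups and 27 without Atm MT replicates 1 to 4. Between DM and Sf3b1 MT (12) there were 4 without a filter, 201 with weights and 22 with Xist. The interaction (0) gave 5 without a filter and 1 without Atm MT replicates 1 to 4. Between DM-CLL and DM (3084) there were 1622 after scaling, 1779 with weights, 1247 with the block and 1644 with only these groups. In that comparison there were 1539 with immunoglobulin genes out and the table rescaled, against 1491 with the whole table rescaled and no gene removed. There were 1502 without ribosomal protein genes and with the rest rescaled. Between DM-CLL and WT (1299) there were 755 with the block and 778 with only these groups. Leaving out 1 library of the groups compared at a time gave 0 to 23 for Sf3b1 MT against WT, 19 to 198 for Atm MT against WT, 10 to 318 for DM against WT, 7 to 864 for DM against Atm MT, 0 to 2 for DM against Sf3b1 MT, 0 to 1 for the interaction, 1504 to 3206 for DM-CLL against DM, 696 to 1237 for DM-CLL against WT, and, over all libraries, 104 to 124 list calls and 0.286 to 0.465 for the correlation of Sf3b1 effects. Libraries of other groups, which share the estimate of spread, moved the counts of 4 comparisons by more than 1.5 times, as given with each, and took DM against Sf3b1 MT up to 18, DM-CLL against DM up to 3345 and DM-CLL against WT up to 1422. Without Atm MT replicates 1 to 4, which act on it in the same way, there were 19 for Sf3b1 MT against WT, 335 for DM against WT and 26 for DM against Sf3b1 MT. The extremes came without Sf3b1 MT replicate 2 and WT replicate 3, WT replicate 1 and Atm MT replicate 6, WT replicate 1 and DM replicate 6, DM replicates 1 and 6, and DM-CLL replicate 4. List calls (114) numbered 0 with an estimated correlation. For the lists that reversed, the direction of the test turned while only the macrophage list passed (adjusted p = 0.0426), and the medians were these. Without Atm MT replicates 1 to 4, they were dendritic markers in Atm MT against WT (0.01), ribosomal proteins there (0.05) and in the interaction (−0.18), macrophage markers in the interaction (0.10) and interferon response in DM against Atm MT (−0.78). Without WT replicate 2 they were ribosomal proteins in Atm MT against WT (−0.14; −0.14 to 0.19 over omissions) and in the interaction (−0.02; −0.37 to −0.02). With the block they were oxidative phosphorylation in Atm MT against WT (−0.11) and interferon response in DM against WT (−0.33). DNA replication in DM against Sf3b1 MT reversed without DM replicate 3 (−0.17; −0.17 to 0.50 over omissions), immediate early genes in DM against Atm MT without DM replicate 1 (−0.44; −0.44 to 0.39), and erythroid markers in DM-CLL against DM without DM-CLL replicate 5 (2.26; −3.41 to 2.26). The labels do not say whether the replicate numbers pair the samples. Of 16 same-numbered pairs, 4 had residuals correlated above 0.1 (−0.363 to 0.364). Such correlations cannot show whether samples were paired, so the block was not taken as a pairing. The share of the most used immunoglobulin variable gene could not be computed from 2 such genes, and the mitochondrial and stromal lists had too few tested genes. Depth is unknown, so its limit on low values could not be stated.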

Other observations

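The fit with Xist as a covariate was chosen after the data were seen. Gm12191, annotated as a processed pseudogene (chromosome 11, 49678710 to 49679057) and singled out after its values were seen, measured 0 to 29.9 TPM in the WT and Sf3b1 MT libraries and 903 to 2928 TPM in the Atm MT, DM and DM-CLL libraries. Of its 324 distinct 25-base words, 92.3% also occur in Rpl30 and 96.9% in Rpl30-ps9. Rpl30 averaged 1590 TPM in WT, 1582 in Sf3b1 MT, 1697 in Atm MT, 1327 in DM and 1596 in DM-CLL.

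The leukaemic libraries differed from each other in genes chosen after their values were seen. Trpm5 measured 20.1 TPM in DM-CLL replicate 4 and 0.89 in replicate 5, the transcription factor Pou2f3 5.05 and 0.11, and the keratin Krt8 82.7 and 2.07. Icos measured 9.59 and 11.7 TPM, so that it did not follow the T-cell gene Cd3e, at 11.9 and 0.39 TPM. Cyp11a1, Avil, Gnb3 and Gng13 were high in both.

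Libraries of 1 group also differed in genes of the sex chromosomes, which the labels do not describe. Xist was at most 0.03 TPM in each Sf3b1 MT library, where Ddx3y measured 3.04 to 12.5 TPM. In DM-CLL Xist measured 9.54 and 116 TPM and Ddx3y 0. In WT Xist measured 38.6, 47.0 and 0.08 TPM, so the mix differed between Sf3b1 MT and WT. The fit with Xist as a covariate called 0 genes between them (920 at an unadjusted p below 0.05 in limma). In DM Xist averaged 9.18 ± 15.9 TPM and Ddx3y 5.63 ± 5.02 (SD, n = 3), so the mix also differed between DM-CLL and DM. For DM-CLL against DM, the fit with Xist as a covariate called 2883 genes, against 3084 without it.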
